A study of Mus musculus with 9 samples.

How the data were processed

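Samples of mouse stem cells on 9 arrays formed 3 groups of 3: ESCs in 2i, EpiSCs in CHIR99021 with XAV939, and EpiSCs in FGF2 with activin. Total RNA was hybridised to a single-colour Affymetrix array, Mouse Gene 1.0 ST per the file headers of the probe annotation. Groups and replicate numbers were taken from the sample titles and strains from the labels. The growth medium, per the labels' protocols, held 10% fetal bovine serum in all groups. The deposited values are log2 expression summaries, 1 per probe set and array, made by the authors with RMA (background correction, normalization between arrays and probe summary) in Partek, per the submitters' processing notes. Versions, and whether other arrays were normalized together with these, are not given in the sources used here. The log2 scale was read from the values, which ran from 3.08 to 14.34 on the first ESC array, with array medians of 5.57 to 5.65. No gene was centred. Detection calls and scanner signals were not used here, so a dim value cannot be told from background, and a fold change against a dim group understates the change where that group is at background.

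Of 35399 probe sets, 21789 carried 1 gene symbol, 1621 several and 11989 none in the probe annotation. Probe sets with several or no symbols were left out of the gene tests. Symbols were updated through gene identifiers to a RefSeq table of assembly GRCm38.p6, in which 19919 of the 19938 genes matched. That table served for names, chromosomes and gene order only, since the build behind the array annotation is not given in the sources used here, and no coordinates are printed. For the 999 genes with more than 1 probe set the probe set with the highest mean over the 9 arrays was kept.

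Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), with all 9 arrays in 1 fit, no covariates and no filter on dim genes. Adjusted p-values are Benjamini-Hochberg values over 19938 genes, with a threshold of 0.05, and a log2 change of 1 marks 2-fold. Standard errors are the moderated ones. Strain could not be a covariate because it goes with cell type. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists within a comparison, then with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. The lists, 293 genes of which 267 were measured, covered pluripotency states, germ layer and extraembryonic markers, feeder cells, signalling targets, epithelial and mesenchymal genes, germline, DNA methylation, imprinting, metabolism, Hox genes, p53 targets, antigen presentation, sex-linked and housekeeping genes. Genes without a probe set of their own, such as T, Tcf7, Gapdh and Cdkn1a, were not analysed here.

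Genes named in the text follow a rule fixed before the data were examined. It took the 6 largest rises and 6 largest falls among called genes whose 3 values in one group all lay above the 3 in the other (chance share 10%), leaving out predicted and clone names. It added a panel of 14 genes and up to 4 members with the largest change of each list described. Genes named outside this rule are marked as such.

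The fit was tested on simulated data for the comparison of CHIR/XAV EpiSCs with ESCs, with the real gene means and spreads and known changes in a random set of genes among 19938. It recovered 98.5% of 67 genes changed by 0.5 log2 units and 100% of those changed by 1 or 2, with 15 false calls among 214. The breakpoint search on chromosome 15 was also tested on 1 simulated set with 2 breaks and placed both within 1 gene of the true positions. It fits 2 breaks by least squares to log2 changes limited to 1.5 in either direction, with at least 20 genes per stretch, among genes above the dimmest 40%. Such genes are called expressed below, a cut on mean level that may let in genes at background.

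Alternatives tried were the mean of all probe sets of a gene, leaving out the dimmest 40% of genes, trend and robust variance, fits of 2 groups alone, median centring, quantile normalization, array weights, replicate number as a block, each array left out, and a limma treat test against 1.5-fold. Leaving out genes on chromosomes X and Y, or on 15, X and Y, was added after the data were seen.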

Results

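Gene expression was measured on 9 microarrays in mouse pluripotent stem cells kept under 3 culture conditions, with 3 arrays per condition. Embryonic stem cells (ESCs), which correspond to the naive epiblast of the early blastocyst, were kept in 2i, a pair of kinase inhibitors: CHIR99021 (3 µM), which inhibits GSK3 and so stabilises beta-catenin, and PD0325901 (1 µM), which inhibits MEK and so blocks ERK signalling. Epiblast stem cells (EpiSCs), which correspond to the later, primed epiblast, were kept either in CHIR99021 (3 µM) with XAV939 (2 µM), a tankyrase inhibitor that stabilises Axin, or in the growth factors FGF2 (10 ng/ml) and activin (10 ng/ml), the usual EpiSC medium. The labels list these doses for all samples together, and the assignment of the 2i pair to ESCs follows the common meaning of that name. The ESCs were of strain 129 and both EpiSC groups of strain CD1, so strain goes with cell type in each comparison against ESCs. So does PD0325901, which is in the ESC medium alone. Changes of ERK targets against ESCs therefore cannot be assigned to cell state rather than to the absence of that inhibitor. Values are log2 expression, with array medians between 5.57 and 5.65. The number of arrays limits the precision, and nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

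Arrays of one group resembled each other closely, and both EpiSC groups resembled each other more than either resembled ESCs. Across 19938 genes, which are not independent replicates, Pearson correlations within groups ranged from 0.996 to 0.998. Between CHIR/XAV and FGF2/activin EpiSCs they ranged from 0.972 to 0.975, between CHIR/XAV EpiSCs and ESCs from 0.945 to 0.947, and between FGF2/activin EpiSCs and ESCs from 0.933 to 0.938. The first principal component held 69.3% of the variance and separated ESCs from EpiSCs, and the second held 24.6%.

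The comparison of CHIR/XAV EpiSCs with ESCs asks how the primed cells kept on CHIR99021 and XAV939 differ from naive cells. Naive pluripotency genes were far lower in these EpiSCs, while genes of the primed epiblast, targets of FGF/ERK signalling and epithelial genes were higher. Pou5f1 (Oct4), the transcription factor that both pluripotent states share, differed little, at 11.59 in CHIR/XAV EpiSCs against 11.33 in ESCs. All 17 measured naive ESC genes fell, led by Nr0b1 (Dax1, an orphan nuclear receptor), which fell by 7.12 on the log2 scale (SE 0.08, adjusted p = 4.9e-16, limma), or 139-fold. Fgf5, a marker of the primed epiblast, rose by 3.61 (SE 0.07) and Otx2, a homeobox factor of the same stage, by 3.65 (SE 0.08).

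Of 19938 genes tested, limma called 9320 at a Benjamini-Hochberg adjusted p under 0.05, 4916 higher and 4404 lower in CHIR/XAV EpiSCs, and 10468 at an unadjusted p under 0.05. At 2-fold or more, 1002 genes were higher and 657 lower. Most calls were small: 62.1% of the called genes changed by under 1.5-fold, and a limma treat test against a change of 1.5-fold called 2241.

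The 6 largest rises were those of Mir302b, Mir302c and Mir302d, of Hprt, of Nr1h5 and of Kcnma1. The 3 microRNA genes belong to the miR-302 cluster, which is expressed in primed pluripotent cells. Mir302b went from 4.48 ± 0.14 to 10.63 ± 0.38 (SD, n = 3), a rise of 6.15. Hprt, which encodes the purine salvage enzyme HPRT, went from 4.75 ± 0.04 in ESCs to 10.39 ± 0.04 (SD, n = 3), and Nr1h5, an FXR-related nuclear receptor gene, rose by 5.59. Kcnma1, which encodes a potassium channel, rose by 5.52 on its brighter probe set, whereas its dimmer probe set differed by -0.42, so the probe sets disagree. Besides Nr0b1, the largest falls were those of Dppa5a (-6.71), an RNA-binding protein gene of pluripotent cells, Triml2 (-5.34), Jam2 (-5.24), Tspan6 (-5.23) and Esrrb (-5.15), a nuclear receptor of the naive network.

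In the fixed panel, Nanog fell by 2.12 but was still at 10.25, and Sox2 fell by 0.77 to 11.03. Zfp42 (Rex1) fell by 3.08, Dppa3 (Stella) by 3.06 and Klf4 by 1.75. The second probe set of Dppa3 changed less, by -2.17. Lefty1, a Nodal antagonist that Nodal signalling itself induces, fell by 4.37, to 4.62. Axin2, a feedback target of Wnt/beta-catenin, fell by 1.00. Dusp6, an ERK-induced phosphatase gene, rose by 4.11 and Cdh1 (E-cadherin) by 0.57. T (Brachyury) had no probe set of its own and was not analysed here.

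**Figure D1:**
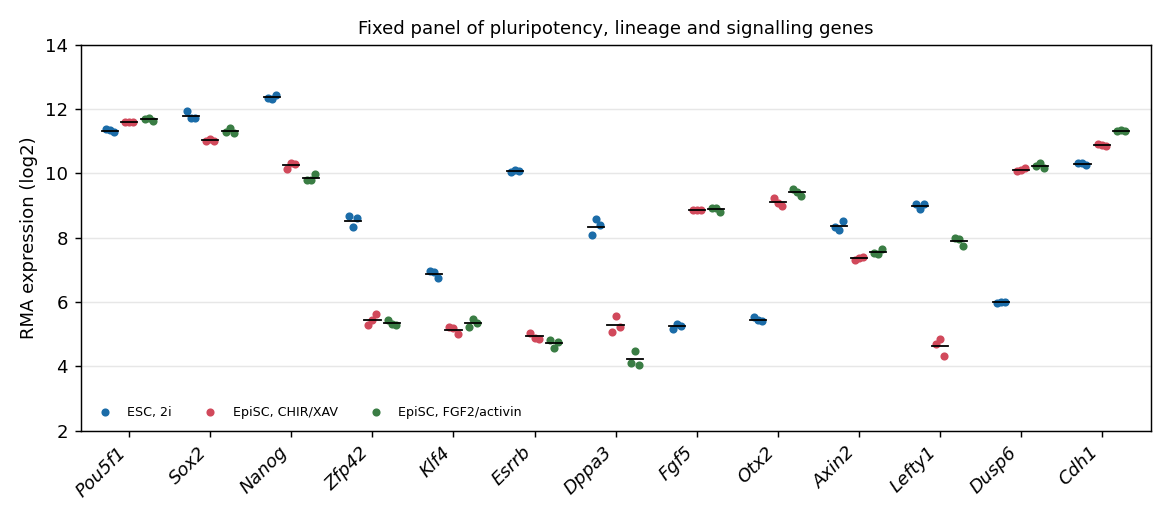
Expression (RMA, log2, vertical axis) of the 13 measured panel genes on each array, with a dot per array and a black line for the group mean of 3 arrays. Pou5f1 lies between 11.33 and 11.68 in the group means, Esrrb, Zfp42 and Dppa3 are highest in ESCs, and Fgf5, Otx2 and Dusp6 are lowest there.

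Of 25 gene lists fixed before the data were examined, camera called 9 in this comparison, 7 higher and 2 lower, and 6 of the 9 calls held with an estimated in place of a preset correlation between genes. In the naive ESC list all 17 members fell (adjusted p = 9.03e-18, median -3.08), among them Tfcp2l1 (-5.10) and Nr5a2 (-4.95). In the primed epiblast list 12 of 15 rose and 1 fell (adjusted p = 3.4e-06), with Cldn6, a tight junction gene, up by 2.72 and the de novo DNA methyltransferase Dnmt3b up by 2.00. Of the 17 FGF/ERK targets 13 rose and 1 fell (adjusted p = 1.53e-07). Spry4, a feedback inhibitor of the pathway, rose by 3.52, Etv4 by 2.42 and Dusp4 by 2.23. Of the 10 epithelial genes 9 rose and 1 fell (adjusted p = 2.46e-06), with Cldn7 (2.44), Grhl2 (2.42), Esrp1 (2.39) and Epcam (2.35) changing most. All 6 measured MHC class I antigen presentation genes rose (adjusted p = 4.69e-06), among them B2m (1.97) and the peptide transporter genes Tap2 (1.75) and Tap1 (1.53). Of 16 imprinted genes 11 rose and 2 fell (adjusted p = 0.00114), with the neighbouring noncoding RNAs Meg3 (2.69) and Rian (2.67) and the zinc-finger gene Plagl1 (2.32) changing most. The counts adjusted over the list alone were the same for these 6 lists.

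The other 3 calls were lost with an estimated correlation. Of 13 germline genes 10 fell and 1 rose (adjusted p = 0.000563, and adjusted p = 0.277 with an estimated correlation), led by Hormad1 (-3.22), Ddx4 (-2.53) and Dazl (-2.51). Of 15 glycolysis genes 11 rose and 2 fell (adjusted p = 0.000503, and adjusted p = 0.231 with an estimated correlation), led by the phosphofructokinase genes Pfkl (2.56) and Pfkm (2.11) and by Ldha (1.61). Of 11 p53 targets 6 rose and 2 fell (adjusted p = 0.0213, and adjusted p = 0.112 with an estimated correlation), and 7 rose when adjusted over the list alone. Plk2 (1.94), Perp (1.57) and Btg2 (1.29) rose most. The germline and glycolysis counts were unaltered when adjusted over the list alone.

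The 15 Wnt/beta-catenin targets went both ways, with 4 rises and 6 falls (adjusted p = 0.447), or 7 falls adjusted over the list alone. Lgr5 (2.92) and Myc (2.74) rose, and Notum (-2.56) and Cdx2 (-1.07) fell. The lists of core pluripotency (6 of 9 rose, 2 fell), DNA methylation machinery (2 of 8 rose, 3 fell), mesenchymal genes (2 of 8 rose, 4 fell), Nodal/activin targets (2 of 8 rose, 3 fell), the beta-catenin destruction complex (2 of 10 rose, 2 fell), cytochrome c oxidase (1 of 10 rose, 4 fell) and Hox genes (1 of 13 rose, 3 fell) were not called. Within the DNA methylation machinery, Tet2, a 5-methylcytosine oxidase gene, fell by 3.53. Of the 8 housekeeping genes 4 rose and none fell, Hprt among the rises. In the 4 sex-linked genes Xist, the RNA that coats the inactive X chromosome, rose by 4.54, while the Y-linked Eif2s3y fell by 4.74 and Uty by 4.56. Marker lists of other cell types were not called: primitive streak and mesoderm (4 of 13 rose, 4 fell), definitive endoderm (0 of 9 rose, 2 fell), extraembryonic endoderm (3 of 12 rose, 2 fell), neural (5 of 12 rose, 2 fell), trophoblast (7 of 11 rose, 2 fell) and fibroblast or feeder (1 of 11 rose, 2 fell). After quantile normalization 2 mesoderm genes, 1 fibroblast gene and 1 Hox gene fell. Single members moved strongly all the same: Fabp7 (3.26) and Nes (2.38) of the neural list and Krt8 (1.63) of the trophoblast list rose, and Trh (-4.11) of the endoderm list and Tfap2c (-2.98) of the trophoblast list fell.

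Genes on chromosome 15 were higher as a set in CHIR/XAV EpiSCs than in ESCs, and Pfkm lies in a stretch of that chromosome where the median gene was higher by 0.94. Pfkm itself was also higher in FGF2/activin EpiSCs than in ESCs, by 1.07. Over 474 expressed genes of the chromosome the median change exceeded that of the other autosomes by 0.33 (camera over 20 chromosomes, adjusted p = 0.000691).

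The comparison of FGF2/activin EpiSCs with ESCs sets the standard primed culture against the naive one. Here too the naive genes fell and primed epiblast, FGF/ERK, epithelial and antigen presentation genes rose. Dppa5a fell by 7.72 (SE 0.11, adjusted p = 2.49e-15, limma), or 211-fold, and Esrrb by 5.36. Fgf5 rose by 3.63 and Otx2 by 3.95, and Pou5f1 was higher by 0.35. p53 targets were higher as well. Of 11 trophoblast genes 7 rose, keratins most, and 3 fell, and the call of that list was lost with an estimated correlation (adjusted p = 0.0924), without the dimmest 40% of genes (adjusted p = 0.101) and without chromosomes 15, X and Y (adjusted p = 0.213).

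In this comparison limma called 12218 genes, 5537 higher and 6681 lower, with 13100 at an unadjusted p under 0.05. The balance depends on the scaling: 45.3% of the calls were higher as deposited, 55.1% after median centring, 51.2% after quantile normalization and 59.6% without the dimmest 40% of genes. At 2-fold or more 1327 were higher and 688 lower. Among all calls 66.3% were under 1.5-fold, and the treat test against 1.5-fold called 2726. The largest rises were those of Hprt (5.62), Mir302b (5.58), Thbs1 (5.40), which encodes the matrix protein thrombospondin 1, the semaphorin gene Sema6a (5.37), Mir302c (5.27) and the epithelial keratin gene Krt19 (5.22). After Dppa5a, the largest falls were those of Pla2g1b (-6.34), a secreted phospholipase gene, Jam2 (-5.79), Nr0b1 (-5.67), Triml2 (-5.60) and Esrrb.

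In the panel, Nanog (-2.51), Sox2 (-0.47), Zfp42 (-3.19), Klf4 (-1.53) and Dppa3 (-4.12) fell. The second probe set of Dppa3 changed less, by -2.44. Dusp6 rose by 4.24 and Cdh1 by 1.02, Axin2 fell by 0.81, and Lefty1 fell by 1.10 to 7.89.

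Camera called 11 lists, 8 higher and 3 lower, and 6 of the calls held with an estimated correlation. Of the 17 naive ESC genes 16 fell and 1 rose (adjusted p = 1.1e-12), or none rose after quantile normalization, with Nr5a2 (-5.05) and Tfcp2l1 (-4.63) among them. Of 15 primed epiblast genes 14 rose (adjusted p = 1.78e-07), among them Cldn6 (3.40) and Sox4 (1.99). Of the FGF/ERK targets 15 rose and 1 fell (adjusted p = 8.49e-09), led by Spry4 (4.31), Dusp6, Phlda1 (3.07) and Egr1 (2.57). Of the epithelial genes 8 rose and 1 fell (adjusted p = 5.03e-05), led by Cldn7 (2.71) and Esrp1 (2.61). Of the p53 targets 10 rose and 1 fell (adjusted p = 1.62e-05), led by Perp (3.46), a desmosome gene, Plk2 (2.89) and Btg2 (2.14). All 6 MHC class I genes rose (adjusted p = 0.000121), led by B2m (2.32) and Tapbp (2.32). The counts adjusted over the list alone were the same for these 6 lists.

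The other 5 calls were lost with an estimated correlation. The germline list, with 11 of 13 members lower and 1 higher, had an adjusted p = 2.35e-06, and an adjusted p = 0.0924 with an estimated correlation. The synaptonemal complex gene Sycp3 was at 5.015 against 9.02 in ESCs, and the piRNA pathway gene Mael fell by 3.41. The glycolysis list, with 12 of 15 higher and 1 lower (2 lower after quantile normalization), had an adjusted p = 1.62e-05, and an adjusted p = 0.0924 with an estimated correlation. Pfkl rose by 2.52 and Ldha by 1.65. The imprinted list, with 10 of 16 higher and 2 lower, had an adjusted p = 0.00216, and an adjusted p = 0.053 with an estimated correlation. Plagl1 rose by 3.29, Peg10 by 1.73 and Igf2, a fetal growth factor gene, by 1.69. The trophoblast list, with 7 of 11 higher and 3 lower, had an adjusted p = 0.0178, and an adjusted p = 0.0924 with an estimated correlation. Its largest rises, Krt18 (3.95) and Krt8 (3.79), are those of keratins of simple epithelia in general, and Eomes (2.32), a T-box factor, also marks the primitive streak. Tfap2c of the same list fell by 1.78. Without genes on chromosomes 15, X and Y, a setting chosen after the data were seen, the list's call was lost (camera, adjusted p = 0.213), with a median of 1.06 against 1.07. That setting takes out Krt8 and Krt18, which lie on chromosome 15. The Hox list, with 10 of 13 lower, had an adjusted p = 0.0303, and an adjusted p = 0.0924 with an estimated correlation. These genes were dim in all groups, with Hoxa7 at 5.82 in ESCs against 4.97, and after quantile normalization only 3 of them fell. Counts adjusted over the list alone were the same for these 5 lists.

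Among lists without a call, the Wnt/beta-catenin targets had 7 rises and 6 falls, or 4 and 5 after quantile normalization, with Lgr5 (2.73) and Myc (2.66) up and Notum (-2.62) down. Wnt3 (2.36) and Eomes rose within the primitive streak and mesoderm list, of whose 13 members 4 rose and 5 fell, or 4 and 2 after quantile normalization. Nes (3.66) and Sox11 (2.76) rose within the neural list, of whose 12 members 5 rose and 3 fell. Sparc (2.39), a matrix gene, rose within the extraembryonic endoderm list, of whose 12 members 5 rose and 6 fell, or 5 and 4 after quantile normalization. In the fibroblast or feeder list 4 of 11 rose, by at most 0.43 (Twist2), and 2 fell, or 1 after quantile normalization. The Y-linked Kdm5d was higher by 3.82 in FGF2/activin EpiSCs than in ESCs, at 8.57 against 4.75, while Eif2s3y and Uty differed by 0.46 and 0.53.

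**Figure D2:**
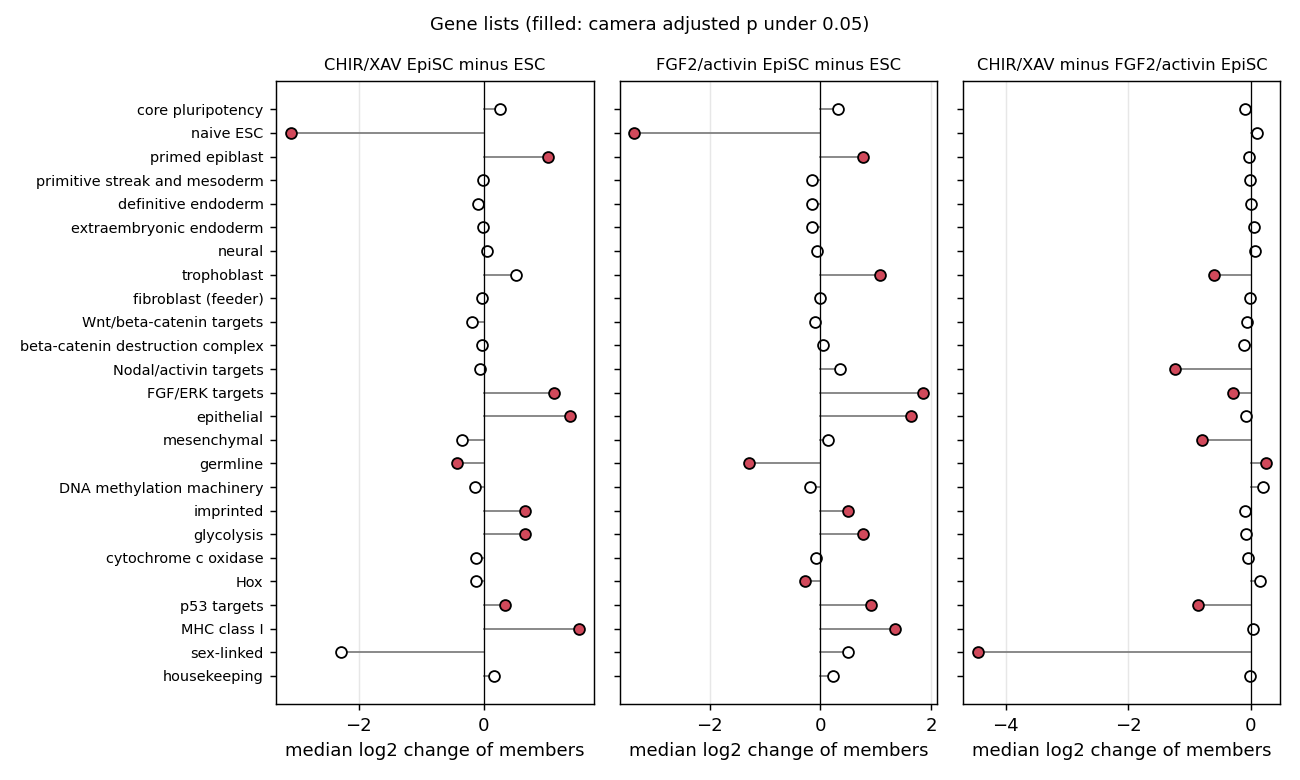
Median log2 change of the measured members (horizontal axis) of each of the 25 gene lists (vertical axis) in the 3 comparisons, each panel on its own scale, with filled dots for lists that camera called. The naive ESC list has medians of -3.08 and -3.36 against ESCs and 0.11 between the EpiSC groups, where the sex-linked list has a median of -4.46.

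Both EpiSC groups were then set side by side to ask which differences from ESCs they share. In the same direction in both, 3627 genes rose and 3195 fell, 6822 together, and 642 went in opposite directions. At 2-fold or more 680 genes rose and 439 fell in both, and 14 went opposite ways. Nr0b1, Dppa5a, Esrrb, Jam2 and Triml2 were among the falls and Hprt, Mir302b and Mir302c among the rises. Independent lists of these sizes would share 66.7 rises and 22.7 falls at 2-fold or more, and 1365 rises and 1476 falls at any size.

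Both comparisons use the same 3 ESC arrays. In 100 simulations of unchanged groups with a shared control the calls shared 0 genes (limma, adjusted p under 0.05). With no true change almost no gene is called, and independent lists of the simulated sizes would share a mean of 5.02e-07 rises. The 0 was therefore fixed in advance and is no test of the overlap. The log2 changes correlated across genes with r = 0.779, against a mean of 0.499 in the simulations. Their covariance was 0.358 against a simulated 0.00356. With 3 ESC arrays the controls could not be split into sets of at least 2. The simulations already contain the shared arrays, so the spread between arrays, as simulated, does not account for the excess. A deviation common to all 3 ESC arrays was not simulated. Simulations of unchanged groups also cannot show what is peculiar to these ESCs, such as their strain, which both comparisons would share. Of 2541 genes changed at 2-fold or more in either EpiSC group, 676 (26.6%) also differed at 2-fold or more between the EpiSC groups.

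The comparison of CHIR/XAV with FGF2/activin EpiSCs asks how the 2 primed cultures differ. The naive and primed lists were not called between them, but many of their members were: of 17 naive genes 6 rose and 5 fell, or 3 and 6 after median centring and 4 and 6 after quantile normalization, and of 15 primed genes 4 rose and 6 fell. Nr0b1 differed by -1.44, Dnmt3b by 1.23 and Nodal by -1.33, whereas Fgf5 differed by -0.03 (adjusted p = 0.799), Pou5f1 by -0.09 (adjusted p = 0.291) and Zfp42 by 0.11 (adjusted p = 0.427, limma). Targets of Nodal/activin signalling were lower in CHIR/XAV EpiSCs, Lefty1 by 3.28 (SE 0.11, adjusted p = 3.98e-11), or 9.68-fold, though the call of that list was lost with an estimated correlation (adjusted p = 0.0811). Among called lists, p53 targets, trophoblast genes and mesenchymal genes were also lower, and germline genes were higher. With an estimated correlation only the p53 call held, and those of trophoblast (adjusted p = 0.0644), mesenchymal (adjusted p = 0.274) and germline genes (adjusted p = 0.274) were lost. The groups differed in sex-linked genes as well, with Xist higher by 4.74 and the Y-linked Eif2s3y lower by 5.20 in CHIR/XAV EpiSCs, and along chromosome 15. Because the labels name no cell line, a difference between these groups cannot be assigned to the medium rather than to the line.

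Limma called 8300 genes, 4087 higher and 4213 lower in CHIR/XAV EpiSCs, with 9885 at an unadjusted p under 0.05. The share of higher calls was 49.2% as deposited, 41.3% after median centring, 49.7% after quantile normalization and 41.2% without the dimmest 40% of genes, so the even split depends on these choices. At 2-fold or more 322 were higher and 498 lower. Among all calls 72.2% were under 1.5-fold, and the treat test against 1.5-fold called 1175. Of the 820 genes at 2-fold or more, 52 lie on the X or Y chromosome and 61 on chromosome 15. Without genes on these 3 chromosomes, a setting chosen after the data were seen, 7561 genes were called and 707 of them changed at 2-fold or more.

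The largest rises were those of Pla2g1b (6.20), Nr1h5 (5.69), the bicarbonate transporter gene Slc4a10 (5.22), Xist, Rnf17 (4.65), which encodes a Tudor-domain protein of male germ cells, and Dppa4 (4.38), a chromatin factor gene of pluripotent cells. Pla2g1b was at 11.91 in CHIR/XAV EpiSCs, 12.06 in ESCs and 5.71 in FGF2/activin EpiSCs, and Dppa4 at 9.24, 8.97 and 4.85. The largest falls were those of Tspan6 (-5.47), Eif2s3y, Uty (-5.08), Slc38a4 (-4.56), an amino acid transporter gene, Kdm5d (-3.84) and Map3k15 (-3.68). Tspan6 and Map3k15 are X-linked. Slc38a4 lies on chromosome 15, in a stretch where the median expressed gene was higher by 0.20 in CHIR/XAV EpiSCs, so its fall runs against its stretch.

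In the panel, Nanog was higher by 0.39 and Dppa3 by 1.07 in CHIR/XAV EpiSCs, Sox2 was lower by 0.30 (-0.30), Otx2 by 0.31 (-0.31) and Cdh1 by 0.45 (-0.45). The size for Dppa3 depends on the probe set, since its second one differed by 0.27. Dusp6 differed by -0.13 (adjusted p = 0.127), Axin2 by -0.20 (adjusted p = 0.0621) and Klf4 by -0.21 (adjusted p = 0.0672). Esrrb, near the dim end in both groups at 4.93 and 4.72, differed by 0.20 (adjusted p = 0.0485), a call that was lost when any 1 of 7 of the 9 arrays was left out.

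Camera called 7 lists, and only the call for p53 targets held with an estimated correlation. For trophoblast and sex-linked genes the estimate (-0.017 and -0.054) was below the preset 0.01. A higher correlation therefore does not account for the loss of their calls. Of the 11 p53 targets 9 fell and none rose (adjusted p = 3.58e-06, and adjusted p = 0.0372 with an estimated correlation). Perp fell by 1.89, Eda2r by 1.09, Phlda3 by 1.02 and Plk2 by 0.95. Of the 8 Nodal/activin targets 7 fell (adjusted p = 5.84e-05, and adjusted p = 0.0811 with an estimated correlation), and 1 rose when adjusted over the list alone. Besides Lefty1, Pmepa1 fell by 1.76, Lefty2 by 1.39 and Nodal by 1.33. Of the 13 germline genes 8 rose, or 5 after quantile normalization, and none fell (adjusted p = 0.000253, and adjusted p = 0.274 with an estimated correlation), led by Sycp3 (3.75) and Mael (3.20). Of the 17 FGF/ERK targets 9 fell and 2 rose (adjusted p = 0.00334, and adjusted p = 0.234 with an estimated correlation), led by Phlda1 (-1.91) and Egr1 (-1.10). Of the 8 mesenchymal genes 5 fell and 1 rose (adjusted p = 0.0103, and adjusted p = 0.274 with an estimated correlation), and 2 rose when adjusted over the list alone, or none after median centring. Fibronectin (Fn1) fell by 1.30 and vimentin (Vim) by 1.13. Without the dimmest 40% of genes the FGF/ERK (adjusted p = 0.143) and mesenchymal (adjusted p = 0.0584) calls were lost, with medians of -0.21 against -0.28 and of -0.82 against -0.80.

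Of the 11 trophoblast genes 8 fell and none rose (adjusted p = 0.000271, and adjusted p = 0.0644 with an estimated correlation). Krt18 fell by 2.72, Krt8 by 2.16, Eomes by 1.28 and Tfap2c by 1.20. Krt8 and Krt18 lie on the distal stretch of chromosome 15 where the median expressed gene was lower by 0.68 in CHIR/XAV EpiSCs (-0.68). The call held without genes on chromosomes 15, X and Y. Adjusted over the list alone, the counts of trophoblast genes, p53 targets, germline genes and FGF/ERK targets were the same.

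Within uncalled lists, Wnt3 fell by 1.39 (primitive streak), Trh by 2.23 (endoderm), Sparc by 1.35 (extraembryonic endoderm) and Nes by 1.28 (neural), while Fabp7 (1.53) and Thy1 (1.51) rose. Of 15 Wnt/beta-catenin targets 2 rose and 6 fell (adjusted p = 0.573), or 7 fell adjusted over the list alone, Sp5 by 0.99 among them. Of 8 genes of the DNA methylation machinery 4 rose and 3 fell, with Dnmt3l (1.98) and Dnmt3b (1.23) higher and Tet3 (-0.88) and Tet2 (-0.46) lower. The second probe set of Tet3 differed less, by -0.44. Among imprinted genes Mest (1.77) and Dlk1 (1.55) were higher and Igf2 (-1.76) was lower. None of the 8 housekeeping genes was called, and 1 was after median centring.

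The Y-linked genes Eif2s3y and Uty were at 9.61 and 9.37 in FGF2/activin EpiSCs, at 9.15 and 8.84 in ESCs, and at 4.41 and 4.28 in CHIR/XAV EpiSCs. Xist was at 9.12 ± 0.29 (SD, n = 3) in CHIR/XAV EpiSCs, 4.38 in FGF2/activin EpiSCs and 4.59 in ESCs. Every CHIR/XAV array differed in this way from every array of the other groups. Kdm5d was high in FGF2/activin EpiSCs alone. Other Y-linked genes, most of them dim, did not all follow: Srsy was lower in CHIR/XAV than in FGF2/activin EpiSCs by 1.20 (-1.20), Sry was higher by 0.26, and Uba1y, Usp9y, Zfy1 and Zfy2 were not called. Expression of Xist, Eif2s3y, Uty and Kdm5d therefore differs between the 2 EpiSC groups. The sex-linked list of the same 4 genes (camera, adjusted p = 0.0054, and adjusted p = 0.107 with an estimated correlation) neither adds to this nor weakens it. Camera asks for movement one way, whereas Xist went opposite to the Y-linked genes. Xist on with Eif2s3y and Uty at the dim end is what a female line would show, and the reverse what a male line would show. The labels name no line, so the design does not separate line from medium.

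**Figure D3:**
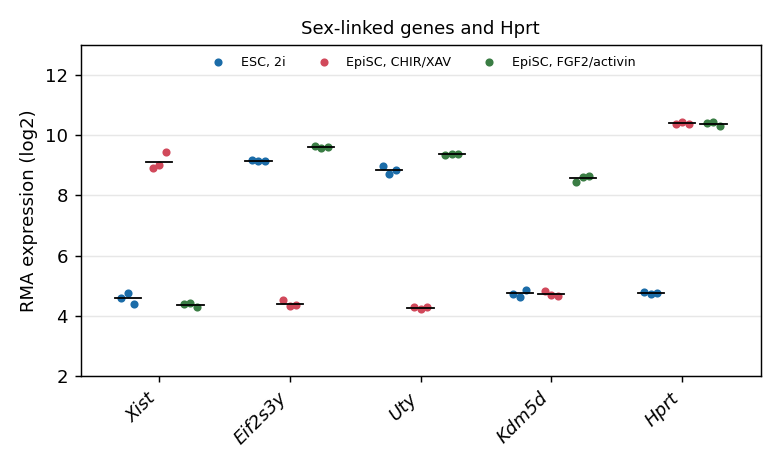
Expression (RMA, log2, vertical axis) of Xist, 3 Y-linked genes and Hprt on each array, with a dot per array and a black line for the mean of 3 arrays. Xist is at 9.12 in CHIR/XAV EpiSCs and below 5 elsewhere, and Hprt is at 4.75 in ESCs and above 10 in both EpiSC groups.

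Chromosome 15 genes, ordered as in the GRCm38.p6 assembly, fell into stretches that moved together in CHIR/XAV EpiSCs. Among 474 expressed genes the best pair of breakpoints left 371 genes from Selenop to Slc38a4, 51 from Amigo2 to Mettl7a1 and 52 from Slc11a2 to Ppp1r1a. Their median differences between CHIR/XAV and FGF2/activin EpiSCs were 0.20, 0.94 and -0.68, and against ESCs 0.39, 0.94 and -0.56. Between FGF2/activin EpiSCs and ESCs they were 0.16, -0.03 and -0.03. All CHIR/XAV arrays lay above all 6 other arrays for 41.5% of the genes in the first stretch and 84.3% in the middle one. Elsewhere 12.8% of autosomal genes did so. In the distal stretch all CHIR/XAV arrays lay below all others for 59.6% of the genes, against 14.04% of autosomal genes elsewhere. By chance either share would be 1.19%. The breaks were placed on the changes between the EpiSC groups in these same genes. The search itself therefore raises the shares inside the stretches over those of unsearched genes, and the contrast is no test. The distal stretch holds Acvr1b, which encodes the activin receptor ALK4 and was lower by 1.09 in CHIR/XAV EpiSCs (-1.09), Krt8, Krt18 and Itga5. Acvr1b and Itga5 were named after their values had been seen. None of 1000 shuffled gene orders gave breaks as sharp. The per-array shift of the whole chromosome against other autosomes was 0.20 ± 0.02 in CHIR/XAV EpiSCs, -0.11 ± 0.01 in ESCs and -0.08 ± 0.01 in FGF2/activin EpiSCs (SD, n = 3), with an exact two-sided permutation p = 0.0119 for CHIR/XAV against the other 6 arrays, the smallest that 84 splits can give. Chromosome and group were picked after their values had been seen, and this p is not adjusted for that choice. It also counts arrays that may be technical repeats as separate.

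**Figure D4:**
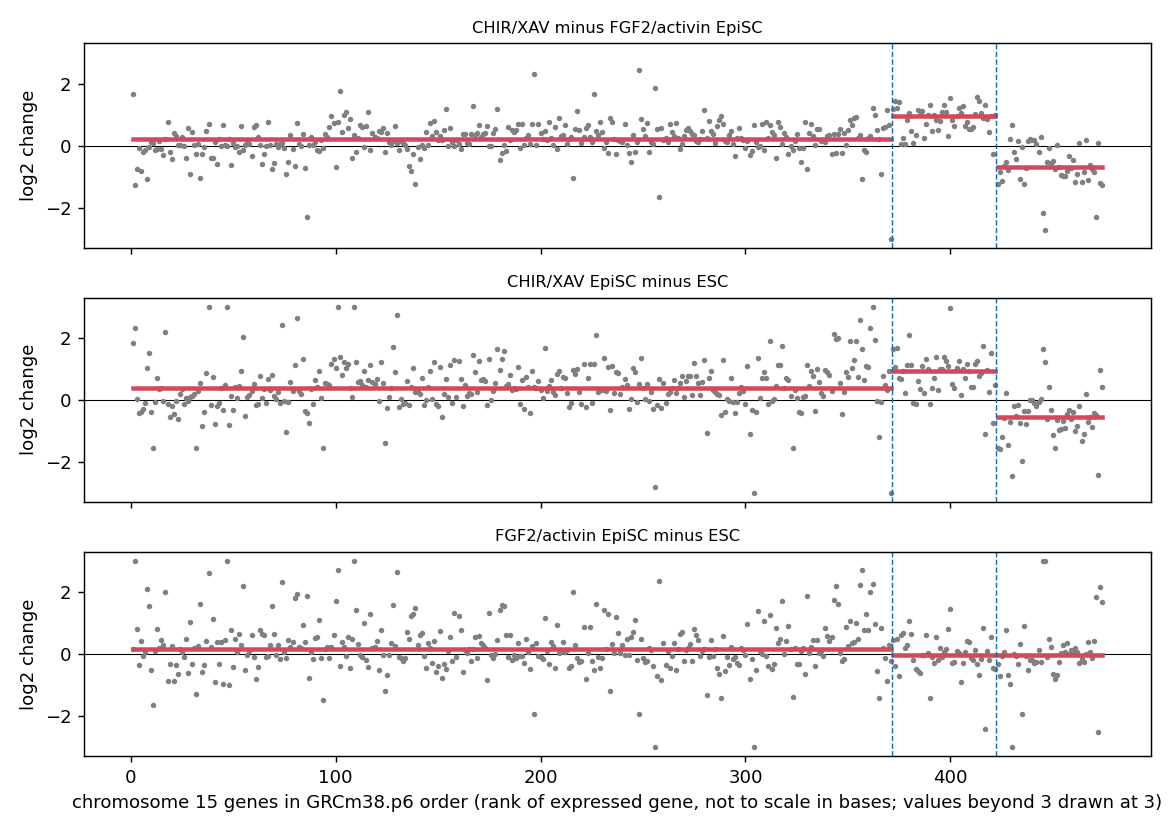
Log2 change (vertical axis) of each of the 474 expressed chromosome 15 genes against its rank along the chromosome (horizontal axis, gene order in GRCm38.p6) in the 3 comparisons, with red lines for the medians of the 3 stretches and dashed lines for the breaks. In the last stretch the medians are -0.68 and -0.56 in the comparisons with CHIR/XAV EpiSCs and -0.03 between FGF2/activin EpiSCs and ESCs.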

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

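Probe sets outside the gene tests also changed between the groups. Among the 11989 probe sets without a gene name, 407 changed at 2-fold or more between CHIR/XAV EpiSCs and ESCs, 385 between FGF2/activin EpiSCs and ESCs, and 161 between the EpiSC groups (limma, adjusted p under 0.05). Among the 1621 probe sets that carry several gene names, 181, 170 and 58 changed at 2-fold or more in the same 3 comparisons. The strongest of these against ESCs included a probe set shared by the genes of the Zscan4 cluster, which mark a transient state of naive ESCs, with changes of -4.45 in CHIR/XAV and -4.16 in FGF2/activin EpiSCs. A probe set shared by the interferon-inducible genes Gbp2 and Gbp2b changed by 4.12 and 5.69. These probe sets were singled out after their values had been seen, and the signal of each cannot be assigned to a single gene.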

How the results depend on the processing

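All settings were chosen before the data were examined except the 2 that leave out whole chromosomes. The counts of called genes in the 3 comparisons and in both EpiSC groups stayed within 1.5 times of the reported ones under all settings but the treat test against 1.5-fold, whose stricter null gave 2241 genes for CHIR/XAV EpiSCs against ESCs, 2726 for FGF2/activin EpiSCs against ESCs, 1175 between the EpiSC groups and 1527 in both EpiSC groups against ESCs. With any 1 array left out the 4 counts ranged from 8438 to 9268, from 10561 to 12416, from 6923 to 8418 and from 6092 to 6800. The share of FGF2/activin calls that were higher than in ESCs was 45.3% as deposited, 55.1% after median centring and 51.2% after quantile normalization, so the balance of small changes depends on the scaling, whereas at 2-fold or more it was 65.9%, 69.7% and 62.4%. Replicate numbers did not pair the arrays: deviations of same-numbered arrays from their group means correlated between -0.07 and 0.24, and a fit with the replicate block called 9325, 12202 and 8246 genes in the 3 comparisons and 6827 in both. Of 27 calls of gene lists, 14 were lost with an estimated correlation, as given beside them. Without the dimmest 40% of genes 7 were lost: those of p53 targets in CHIR/XAV against ESC (adjusted p = 0.164), of trophoblast (0.101), imprinted (0.0818) and Hox genes (0.143) in FGF2/activin against ESC, and of FGF/ERK (0.143), mesenchymal (0.0584) and sex-linked genes (0.0711) between the EpiSC groups. The Hox call was also lost after quantile normalization (0.142). Without genes on chromosomes 15, X and Y the trophoblast call in FGF2/activin against ESC was lost (0.213). Most medians stayed near those of the main fit, with 0.40 against 0.33 for p53 targets, 1.11 against 1.07 for trophoblast, 0.55 against 0.50 for imprinted, -0.46 against -0.29 (and -0.16 after quantile normalization) for Hox, -0.21 against -0.28 for FGF/ERK, -0.82 against -0.80 for mesenchymal and -4.46 in both for sex-linked genes, and 1.06 for trophoblast without the 3 chromosomes. The causes of these losses were not tested, though leaving out the 3 chromosomes takes the chromosome 15 genes Krt8 and Krt18 out of the trophoblast list. No list call reversed. Among lists whose calls were lost with an estimated correlation, the estimate was below the preset 0.01 for trophoblast (-0.017), p53 targets (-0.005), Hox (-0.005), sex-linked (-0.054) and imprinted genes (0.009). For these lists a higher correlation does not account for the loss. The estimate was higher than the preset for the others, such as germline genes (0.269). Of 6658 values of named genes over all settings, 6431 kept their direction and their side of the threshold, 181 lost the call, 40 gained one, and 6 small uncalled differences changed sign. The alternative that drops probe sets with cross-hybridising identifier endings could not be run, because the identifiers on this array carry no such endings. Dim genes limit what can be read, since no background level was used here.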

Other observations

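Tests on chromosome 15, on ESC RNA, on Y loss and on the spread between arrays were chosen after the result was seen, as were the genes of the next paragraph. The tests on escape genes, on quantile normalization and on other splits of the arrays were written down before their results. For chromosome 15 several tests were tried in turn. The first set asked about an extra copy of the whole chromosome and about 4 equal parts of it, whose shifts between the EpiSC groups were 0.061, 0.328, 0.341 and 0.273, and it was replaced after values along the chromosome had been seen. The stretches were then drawn on the same values that they are tested on. The share of lower distal genes was first taken in genes of similar level in ESCs and FGF2/activin EpiSCs, then above 4 cuts of the mean level, and then above the median gene, a cut picked after the others had been seen. A comparison of the distal stretch with random gene sets of like level was dropped, since those sets went through no search for breaks.

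The 5 genes of the miR-302 cluster rose in both EpiSC groups against ESCs, with changes from 3.49 (Mir367) to 6.15 (Mir302b) in CHIR/XAV and from 2.89 to 5.58 in FGF2/activin EpiSCs. Other single genes were picked after their values had been seen, with no test of a gene set, in a comparison of the EpiSC groups where 41.6% of all genes were called. Actc1 (cardiac actin) was at 10.40 in FGF2/activin against 6.84 in CHIR/XAV EpiSCs, Acta2 (smooth muscle actin) at 9.41 against 5.96, and Cav1 (caveolin) at 7.89 against 4.88, while Ccn2 and Cnn1 went the other way. Nqo1 was higher in CHIR/XAV EpiSCs by 3.91, Gstp1 by 3.76 and Slc7a11 by 3.22, with Nqo1 at 9.07 in CHIR/XAV EpiSCs, 9.08 in ESCs and 5.15 in FGF2/activin EpiSCs, whereas Hmox1 differed by 0.11 (limma, adjusted p = 0.216).

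Hprt was at 4.75 in the ESCs and at 10.39 and 10.38 in the EpiSC groups, while no other measured gene of the housekeeping list, on the probe set used, differed from ESCs by more than 0.36 in either group. A second bright probe set of Rplp0 disagrees with the one used (0.36 and 0.24), being higher than in ESCs by 1.14 in CHIR/XAV and by 0.92 in FGF2/activin EpiSCs. Some ESC lines of strain 129 carry a loss of Hprt, and the labels used here name no line. Kdm5d was at 4.75 in ESCs although Eif2s3y and Uty were at 9.15 and 8.84 there. Among windows of 20 neighbouring expressed genes over all chromosomes, the window of chromosome 12 that starts at Mir665, in the imprinted region of Meg3 and Rian, was higher by 0.90 in CHIR/XAV EpiSCs than in ESCs, beyond the 0.64 reached in 100 shuffles of gene order. On the X chromosome the windows that start at Tsx (0.65) and Rpl36a (0.68) passed the same bound. Between the EpiSC groups the window of chromosome 10 that starts at Slc6a15 was lower by 0.57 in CHIR/XAV EpiSCs (-0.57), beyond a bound of 0.49, and the other windows past these bounds lie on chromosome 15.

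Xist and 3 Y-linked genes set the EpiSC groups apart. ESC RNA carried over into the FGF2/activin samples, as a source of their Y-linked signal, is argued against by Esrrb, which lay 5.36 below its ESC level there (-5.36). Loss of the Y chromosome from a male line is argued against by Xist, higher by 4.74 in CHIR/XAV EpiSCs. A female line in CHIR/XAV and a male line in FGF2/activin remains a candidate explanation: Kdm5c, Kdm6a and Eif2s3x, which escape X inactivation, stood 0.14 above the X-linked median between the groups, under the 0.2 set beforehand but within the error of 3 genes, so it cannot be told apart from other sources of this pattern. If the lines do differ, differences between the media and between the lines cannot be separated in any gene. The medium alone, acting on a single line, would have to raise Xist and lower the 3 Y-linked genes together, and this was not tested.

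Chromosome 15 genes in CHIR/XAV EpiSCs moved by stretches against both other groups, up most in the middle stretch and down at the distal end. The first and longest stretch was higher too. Of its 371 genes, 138 were called higher than in both other groups and 16 were called lower. An intensity-dependent difference between arrays is argued against, since 0 of 1000 shuffles that exchanged genes of like mean level, with the breaks searched again each time, gave breaks as sharp. Separate responses of single genes to the medium, whatever their place, are argued against by 0 of 1000 shuffled gene orders with breaks as sharp. A copy-number gain next to a loss of the distal end cannot be told apart from regional control of transcription in that medium: of 28 distal genes within 0.3 between ESCs and FGF2/activin EpiSCs, 21 (75%, exact 95% interval 55.1 to 89.3, across the 65% set as the bound) were lower in CHIR/XAV than in FGF2/activin EpiSCs, as were 39 of all 52, and DNA was not measured here. Among brighter genes the share was 37 of 47, 34 of 36, 25 of 27 and 11 of 11 above levels of 5.5, 6, 7 and 8, and 20 of 22 (90.9%) above the median gene, which does not settle the question because the cut was picked on these values.

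Most called genes changed by under 1.5-fold. An intensity-dependent difference between arrays, left by the authors' normalization, cannot be told apart from small true differences as a cause. After quantile normalization 10366 genes were still called between FGF2/activin EpiSCs and ESCs, 60.7% of them under 1.5-fold. That count does not decide it, because RMA had already normalized between arrays. As deposited, the median change in this comparison differed with level. It was -0.148, -0.192, -0.027, 0.182 and 0.099 in groups of genes with mean levels of 4.47, 4.97, 5.86, 7.53 and 9.71. A small spread between arrays that were not separate cultures cannot be told apart from many small true differences: the median standard error was 0.0786, and no value in the files tells cultures from repeat preparations. Other splits of the arrays bear on chance. In each comparison of 2 groups only 1 of the 10 splits of the 6 arrays, the real one, called as many genes (9320, 12218 and 8300, against 0 for the highest of the others), too few splits for a share under 0.05. For genes changed in both EpiSC groups 1 of 100 splits, the real one, gave 6822 and the highest other 4768. Splits that mix the groups have a wider spread, which by itself lowers their counts. They also exchange arrays as if each were a separate culture, so chance between cultures is not excluded.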
